A study of Mus musculus with 786 samples.

How the data were processed

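Early blood-forming cells of mouse bone marrow were profiled by RNA sequencing, as single cells and as sorted bulk populations. The mice were C57BL/6 animals of 6 to 8 weeks, and cells were sorted by surface markers, per the labels' protocols. Haematopoietic stem cells (HSC) were sorted as CD48-, CD150+, CD135- and CD34-, and the first multipotent precursors (MPP1) as the same but CD34+. Single cells were captured in plates of 96 wells and amplified by the Smart-seq protocol. The 672 wells used came from 7 plates: HSC plates 1, 2 and 3, MPP1 plates 1 and 2, and 1 plate each of HSC and of MPP1 from mice that had been bled. Each well's label gives the number of cells it held. The bulk libraries came from 18 sorted populations of 1000 cells each, with 1 library per population. A further 96 samples, a repeat run of HSC plate 1, were not analysed here as such; they share wells and cell numbers with HSC plate 1, so its columns could hold either run.

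The authors deposited FPKM values (fragments scaled to transcript length and to the mapped fragments of the library), 1 value per gene and library. TopHat 1.3.3 and Cufflinks 1.2.1 with the mouse genome build mm9 are named in the submitters' processing notes, and Bowtie2 2.2.1 is named in addition for HSC plate 3. FPKM is scaled within each library, so the values are relative to the total of their own library. The single-cell tables list 21664 genes, and 18855 genes stand in the bulk table. HSC plates 1 and 2 and both MPP1 plates stand in 1 table, the bled plates in another and HSC plate 3 in a further one, and the tables were made separately. The label of HSC plate 3 names an RNA spike-in, but no spike-in row was used here. HSC plate 3 is labelled as an HSC replicate, while its growth note names normal and bled mice together.

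Read depth is unknown, because low FPKM values did not fall on steps that would give whole reads. No confidence interval for a level could therefore be computed, and the exact binomial intervals (Clopper-Pearson, 95%) given for shares of cells cover counting error only. The total FPKM of the cells used had plate medians between 210791 and 286197. Some genes are listed at exactly 0, which can be a failed estimate as well as absence, and such values are given as listed at 0.

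Cells entered if the well's label gave exactly 1 cell and if at least 1000 genes reached FPKM 1. Of 460 wells with 1 cell, 373 passed. Cells are not replicates. The replicate was the plate, which the labels number as a biological replicate, so n was 2 plates per group for normal HSC and MPP1 and 1 plate for each bled group. Nothing in the labels says whether the cells of a plate came from 1 mouse or were pooled. No pair of columns held identical values.

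For each plate and gene the mean FPKM over cells was taken, and log2(mean FPKM + 1) was tested with limma 3.58.1 in R 4.3.3, with an intensity trend and empirical Bayes moderation, in genes with a mean of at least FPKM 1 over the plates. Differences are on this log2(FPKM + 1) scale, which understates the change of low genes. MPP1 was compared with HSC over plates 1 and 2 of each. Bled was compared with normal over 6 plates with cell type as a covariate. This tests the difference averaged over the 2 cell types, so 1 cell type can carry a call. The threshold was an adjusted p (Benjamini-Hochberg) of 0.05, two-sided. Gene lists were tested with camera at a preset correlation of 0.01 between genes, with camera at an estimated correlation and with fry beside it, adjusted over the lists with at least 3 tested genes.

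The tests, the 23 gene lists and the rule for naming genes were fixed before the data were examined. The lists are an HSC program, quiescence regulators, S phase, G2/M phase, megakaryocyte, erythroid, heme synthesis and iron, granulocyte-monocyte, lymphoid, immediate early, interferon response, glycolysis, oxidative phosphorylation, ribosomal proteins, unfolded protein response, sort markers, housekeeping genes, and 6 lists of markers of other cells (B and plasma, T and NK, neutrophil, macrophage, mast and basophil, endothelium and stroma). Some genes stand in more than 1 list, such as Ly6a in the HSC program and the sort markers. Symbols were matched through the RefSeq annotation of GRCm38.p6, used for names only: 21195 single-cell and 18326 bulk genes matched by accession, 322 and 256 by symbol, 94 and 164 by synonym, and 53 and 109 did not match. The rule named up to 10 genes per direction past the threshold with a log2 difference of at least 0.5, every list member that passed, and up to 3 members per list with the smallest p. For the bled plates it named up to 5 genes per direction by the distance to the nearer normal plate, and for the bulk populations the sort markers, the 3 members per list with the widest range, and up to 5 genes per direction between HSC and MPP1. Genes named outside this rule were chosen after their values were seen, and are marked so. A gene that the rule names is not reported here.

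Per bled cell type, and in the bulk populations, no test was made of a group alone, and the median of a list was set against 10000 random lists matched on mean expression. The random lists were not matched on co-variation, so these percentiles do not allow for genes that move together. The difference between the bled effects of the 2 cell types was tested after it was seen. Co-variation of a list was the mean pairwise Spearman correlation over the cells of a plate, after regressing each gene on the number of genes detected per cell, set against 1000 random lists matched on mean expression and share of cells. A list counted as co-varying above the 95th percentile. Cells with at least 3 G2/M genes at FPKM 1 were counted, and plates were compared by exact permutation. Bulk populations were compared by the number of genes with a log2 difference of at least 2 (4-fold) and FPKM 5 in the higher population. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.

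The tests were checked on simulated plates with the real genes and spread. Of 200 changed genes in the HSC and MPP1 design (9833 genes), limma recovered 0% at a log2 change of 1, 8.5% at 2 and 89% at 4. In the bled design (10017 genes) it recovered 0%, 9% and 97%. At a log2 change of 4, 11 and 16 unchanged genes were called in the 2 designs, and with no change 0 and 2. In cells with shuffled values, 2 of 17 lists exceeded the 95th percentile of co-variation. Alternatives changed the pseudocount (0.1 or 5), the filters on genes and wells, the averaging, the scaling, the plates, the replicate block, and the correlation used for lists; their effects stand in the closing section.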

Results

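The series asked how the earliest precursors of mouse blood differ from each other, and how single cells within 1 sorted population differ. Single-cell profiles of HSC and of MPP1, from normal and from bled mice, were compared, and 18 bulk populations from HSC to pro-erythrocytes served as a map of the later lineages. After filtering, 50, 53 and 73 cells remained on HSC plates 1, 2 and 3, 51 and 48 on MPP1 plates 1 and 2, 48 on the bled HSC plate and 50 on the bled MPP1 plate. The median number of genes detected at FPKM 1 was 2157.5, 2594 and 1969 in the HSC plates, 2535 and 2520.5 in the MPP1 plates, 2443 in the bled HSC plate and 3046.5 in the bled MPP1 plate. Bulk libraries held between 1642 genes at FPKM 1 (mature megakaryocytes) and 6080 (GMP-7, a gate for granulocyte-macrophage progenitors).

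First, the number of genes detected per well was set against the number of cells in the well's label. Wells with 1 cell held 1844 ± 375 more genes than wells with no cell (mean and SD of the difference in medians over 7 plates), with a higher median in 7 of 7 plates (exact permutation p = 0.0156, two-sided, the smallest that 7 plates can give). Wells with 2 or more cells exceeded wells with 1 cell by 664.5 ± 774 genes, in 6 of 7 plates (exact permutation p = 0.0781). HSC plate 2 was the exception, with 2 such wells. Of the 150 wells labelled with no cell, 20 still reached 1000 genes, and 1 of them held 4384.

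**Figure D1:**
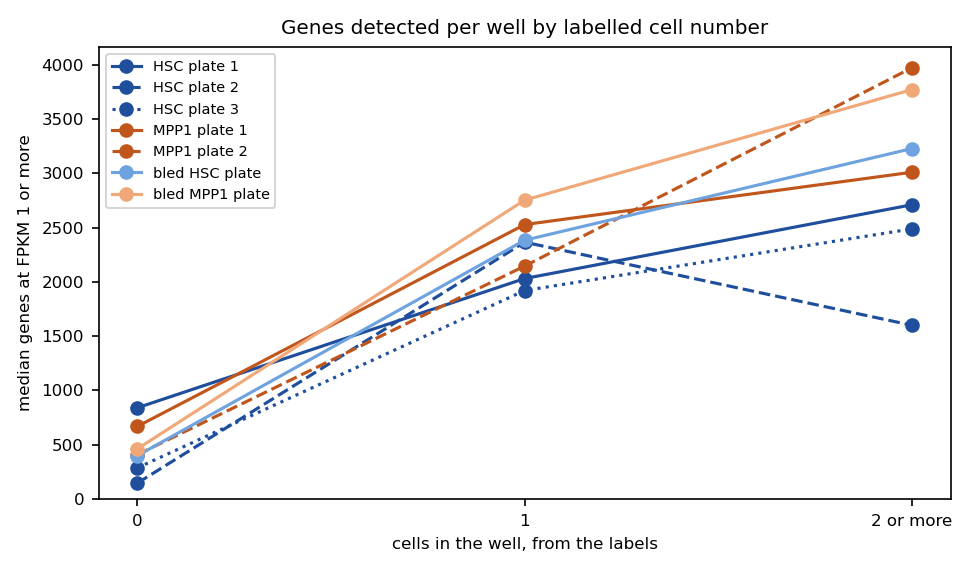
Median genes detected at FPKM 1 or more (vertical axis) in wells labelled with 0, 1, or 2 or more cells (horizontal axis), 1 line per plate. Every plate rose from 0 to 1 cell, and HSC plate 2 alone lay lower with 2 or more cells than with 1 (1600.5 against 2366 genes).

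Next, MPP1 were compared with HSC. Genes of the interferon response, which block virus replication and sense foreign nucleic acid, were lower in MPP1 as a group: 18 of 19 measured genes were lower, with a median log2 difference of -1.84. Ifit1, which binds foreign RNA, had a mean of 88.7 ± 48.0 FPKM in HSC and 8.57 ± 1.86 in MPP1 (SD, n = 2 plates each; log2 difference -3.13, SE 0.62). Zbp1, a sensor of nucleic acids, was at 20.8 ± 10.1 FPKM in HSC and 0.318 ± 0.449 in MPP1 (log2 difference -4.01, SE 0.93). Rtp4 differed by -2.86 (SE 0.63), and Irf7, a transcription factor that drives interferon genes, by -2.57 (SE 0.76). The list was called by camera (adjusted p = 1.01e-13 over 18 lists at the preset correlation; adjusted p = 0.244 with an estimated correlation), and fry gave an unadjusted p of 0.00828. Adjusted over the list alone, 11 genes were lower by limma (Ifit1, Rtp4, Zbp1, Rsad2, Ifit3, Irf7, Ifi44, Mx1, Oasl2, Usp18 and Stat2), against 0 adjusted over all 9833 genes and 13 at an unadjusted p under 0.05. A list gene was detected on average in 23.7% and 27.9% of the cells of HSC plates 1 and 2 and in 11.4% and 11.3% of those of MPP1 plates 1 and 2. HSC plate 3, from another table, stood nearer to MPP1: 13.1% of cells, and a median log2 level of 3.42 against 4.69 and 4.61 in HSC plates 1 and 2 and 3.16 and 1.94 in the MPP1 plates. With HSC plate 3 added, an alternative chosen after seeing the data, the median difference was -1.41 (camera adjusted p = 1.09e-08).

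Immediate early genes, which are transcribed within minutes of a stimulus or of cell handling, went the other way. They were higher in MPP1 in 15 of 16 measured genes, with a median log2 difference of 1.53. Nr4a1, a nuclear receptor, had a mean of 11.7 ± 5.67 FPKM in HSC and 143 ± 53.0 in MPP1 (SD, n = 2 plates each; log2 difference 3.53, SE 0.57). Btg2, an antiproliferative gene, differed by 2.58 (SE 0.60), Atf3, a stress-induced transcription factor, by 2.36 (SE 0.64), and Jun, a subunit of AP-1, by 2.04 (SE 0.52). Camera called the list (adjusted p = 3.17e-10; adjusted p = 0.339 with an estimated correlation; fry unadjusted p = 0.0423). Adjusted over the list alone, 7 genes were higher by limma (Nr4a1, Btg2, Jun, Fosb, Atf3, Klf6 and Ier2), against 0 over all genes. Wells labelled with no cell showed the same direction by a median of 3.27: their median log2 levels were 6.35 and 6.12 on the MPP1 plates and 3.36 and 0.03 on HSC plates 1 and 2. For the interferon genes the HSC minus MPP1 difference in no-cell wells was 0.77. Their median log2 level in these wells was 2.02 on HSC plate 1 and 0 on HSC plate 2 and on both MPP1 plates.

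**Figure D2:**
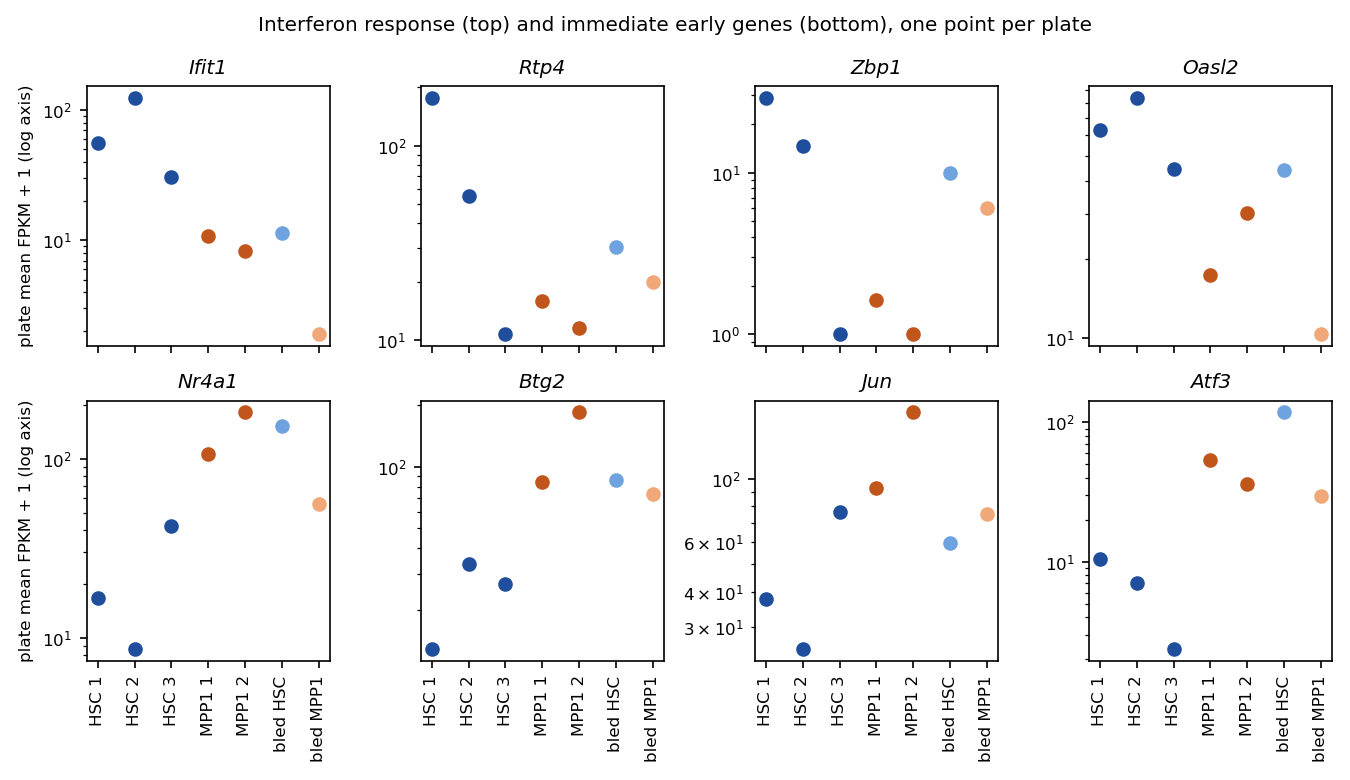
Mean FPKM + 1 per plate (vertical axes, log scale) of 4 interferon response genes (top) and 4 immediate early genes (bottom), 1 point per plate (horizontal axis). Ifit1 lay at 54.7 and 123 FPKM in HSC plates 1 and 2 and at 9.88 and 7.25 in the MPP1 plates, and Nr4a1 at 15.7 and 7.66 against 105 and 180.

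Genes tied to stem cell identity were lower in MPP1 on balance. Of 22 measured genes of the HSC program 18 were lower, with a median log2 difference of -0.67 (camera adjusted p = 0.00332; adjusted p = 0.377 with an estimated correlation). Ly6a, which encodes the sorting antigen Sca-1, had a mean of 368 ± 76.3 FPKM in HSC and 65.0 ± 11.2 in MPP1 (SD, n = 2 plates each; log2 difference -2.48, SE 0.42), and Ifitm1, an interferon-induced membrane protein, differed by -1.76 (SE 0.42). Ctla2a, an inhibitor of cysteine proteases, went against the list and was higher in MPP1 by 2.27 (SE 0.39). These 3 genes passed limma adjusted over the list alone, and 0 passed over all genes. Ly6a was at 159 FPKM in HSC plate 3. In no-cell wells the HSC minus MPP1 difference of this list was -0.23, opposite in direction.

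Single lineage genes stood out within other lists without the list as a whole moving. Pf4, the platelet chemokine, was at 25.4 ± 18.5 FPKM in HSC and 184 ± 64.7 in MPP1 (SD, n = 2 plates each; log2 difference 2.97, SE 0.58), and Plek, the platelet protein pleckstrin, differed by 2.80 (SE 0.83). Both passed limma adjusted over the megakaryocyte list alone, while 9 of 16 list genes were higher and 7 lower (median 0.13, camera adjusted p = 0.173). Of 5 measured lymphoid genes 3 were higher and 2 lower (median 0.82, camera adjusted p = 0.173). Emcn, a sialomucin of endothelium and stem cells and the 1 measured gene of the endothelium and stroma list, was lower in MPP1 than in HSC plates 1 and 2 by -2.01 (SE 0.72, limma p = 0.0152), while HSC plate 3 was at 7.40 FPKM and the MPP1 plates at 7.36 and 10.7. Of the sort markers, Ly6a passed adjusted over the list alone, while Cd34 (35.1 ± 2.80 and 76.7 ± 14.4 FPKM in HSC and MPP1, limma p = 0.0471) and Cd48 (log2 difference 2.46, limma p = 0.0262) were higher in MPP1 at an unadjusted p only (list median 1.14, camera adjusted p = 0.173). Cd48 rested on few cells, detected in 7.84% and 2.08% on MPP1 plates 1 and 2 and in 0% and 1.89% on HSC plates 1 and 2.

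Cell cycle genes leaned towards MPP1. Of 24 G2/M genes 19 were higher in MPP1, with a median log2 difference of 0.56, and 0 passed limma adjusted over the list alone or over all genes (1 at an unadjusted p under 0.05). Plk1, a mitotic kinase, was at 3.27 ± 1.78 FPKM in HSC and 36.2 ± 44.6 in MPP1 (SD, n = 2 plates each), while Ccnb1, the mitotic cyclin B1, was at 13.4 ± 4.78 and 5.25 ± 6.24. Camera called the list (adjusted p = 0.0279; adjusted p = 0.737 with an estimated correlation). Without HSC plate 1 the median was -0.10 (adjusted p = 0.652), without MPP1 plate 2 it was 0.25 (adjusted p = 0.657), and with cells of 2000 or more genes, an alternative chosen after seeing the data, the adjusted p was 0.0931. In no-cell wells the HSC minus MPP1 difference of the G2/M list was -2.30, against -0.56 in wells with 1 cell. Of 21 S phase genes 15 were higher (median 0.23, camera adjusted p = 0.0815).

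The remaining lists were not called. Camera gave adjusted p = 0.293 for erythroid genes (median -0.18), 0.173 for heme synthesis and iron (0.31), 0.533 for granulocyte-monocyte genes (-0.50), 0.293 for glycolysis (0.16), 0.357 for oxidative phosphorylation (0.03), 0.293 for ribosomal proteins (0.12), 0.293 for the unfolded protein response (0.11) and 0.0508 for housekeeping genes (0.41). The quiescence regulators had a median of -0.09 but a mean of 0.09, and camera's direction was up (adjusted p = 0.654); Txnip, which restrains glucose uptake, was at 278 ± 28.1 FPKM in HSC and 123 ± 86.1 in MPP1. The B and plasma list had a median of 0.10 and a mean of -0.39, with camera's direction down (adjusted p = 0.654). Of the other marker lists only 1 or 2 genes were measurable: Klrb1c for T and NK cells (log2 difference 1.54), S100a8 for neutrophils (-0.97), Axl and Cd68 for macrophages (2.17 and -1.20) and Cpa3 for mast cells and basophils (1.81), and 0 of them passed limma adjusted over the list alone. Heat shock genes, a separate list of handling stress, were higher in MPP1 in 8 of 9 cases, with a median of 0.34.

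Over all 9833 genes limma called 1 at an adjusted p under 0.05, and 667 lay at an unadjusted p under 0.05 (252 higher and 415 lower in MPP1). The called gene was Snora30, a small nucleolar RNA named after its values were seen because it is the whole count (log2 difference 8.59, SE 0.63, adjusted p = 2.79e-05). It was listed at 0 in both HSC plates and averaged 419 and 350 FPKM in the MPP1 plates, from 3 of 51 and 2 of 48 cells. Leaving out any of the 4 plates gave 0 called genes. Averaging log2 values over cells instead of FPKM gave 38 (19 higher and 19 lower), among them Nr4a1, Btg2, Atf3 and Plek higher and Ly6a, Ifitm1, Rtp4, Oasl2 and Txnip lower in MPP1.

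Cells with at least 3 G2/M genes at FPKM 1 were then counted. Their share was 20.0% (exact interval 10.0 to 33.7) in HSC plate 1, 43.4% (29.8 to 57.7) in HSC plate 2 and 16.4% (8.79 to 27.0) in HSC plate 3. In MPP1 it was 60.8% (46.1 to 74.2) and 50.0% (35.2 to 64.8). The mean was 31.7% ± 16.5 in HSC plates 1 and 2 and 55.4% ± 7.63 in MPP1 (SD, n = 2 plates each), a difference of 23.7 percentage points (exact permutation p = 0.333, the smallest that 2 against 2 plates can give). In wells labelled with no cell the share was 9.52% and 8.33% on HSC plates 1 and 2 but 60.7% and 46.2% on the MPP1 plates, close to that of their cells. At a threshold of FPKM 5 the difference was 7.71 percentage points, and no-cell wells exceeded cells on MPP1 plate 1 (53.6% against 27.5%) and on MPP1 plate 2 (46.2% against 39.6%). Cells with at least 3 G2/M genes had more genes detected on 7 of 7 plates, from a median of 2030 against 1934 on HSC plate 3 to 3635 against 2521 on the bled MPP1 plate.

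**Figure D3:**
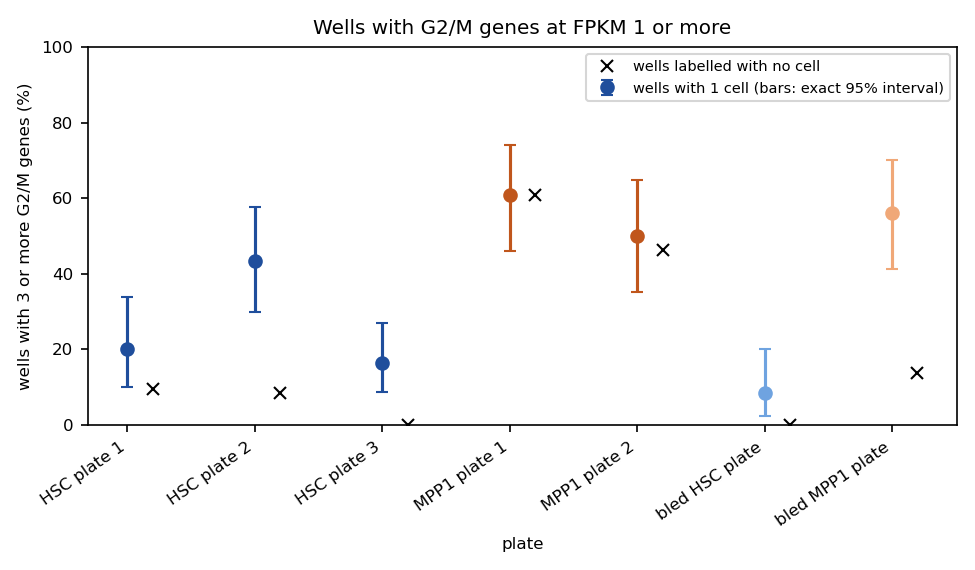
Share of wells with 3 or more G2/M genes at FPKM 1 or more (vertical axis, percent) on each of 7 plates (horizontal axis): circles, wells with 1 cell with their exact 95% interval; crosses, wells labelled with no cell. The crosses lie near the circles on MPP1 plates 1 and 2 (60.7% and 46.2%) and below them on the other plates.

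The next comparison asked what bleeding, which forces the marrow to replace blood, did to HSC and MPP1. Hes1, a Notch-induced repressor counted among the quiescence regulators, was at 0.507 ± 0.242 FPKM in HSC and 3.06 ± 0.00235 in MPP1 (SD, n = 2 plates each), and at 42.5 in the bled HSC plate and 20.7 in the bled MPP1 plate (n = 1 plate each; log2 difference 3.64, SE 0.79). HSC plate 3 also stood high, at 25.7 FPKM. Cdkn1a, the cell cycle inhibitor p21, differed by 2.69 (SE 0.88), and Sult1a1, a sulfotransferase of the HSC program, by 2.67 (SE 0.70). Ifit1 was lower after bleeding by -2.59 (SE 0.59), while Ifit3 was at 48.0 FPKM in bled HSC against 19.4 ± 10.7 in HSC. That mean of Ifit3 rested on 2.08% of bled HSC cells, a lower share than the 4.00% and 13.2% on HSC plates 1 and 2. Limma called 0 of 10017 genes, with 586 at an unadjusted p under 0.05 (340 higher and 246 lower after bleeding). Adjusted over its list alone, 1 gene passed in each of 4 lists: Hes1, Sult1a1, Ifit1, and Cd3d of the T and NK list. Cd3d was listed at 0 on HSC plates 1 and 2 and both MPP1 plates, so it entered the test only through the bled plates. Bleeding, the table and the plate cannot be told apart in this design, since each bled group is 1 plate.

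Genes of oxidative phosphorylation were higher after bleeding in 19 of 21 cases, with a median log2 difference of 0.50. Cox5a, a subunit of cytochrome oxidase, differed by 1.21 (SE 0.45) and Ndufb9, a subunit of complex I, by 0.82 (SE 0.33), and 0 genes passed adjusted over the list alone (3 at an unadjusted limma p under 0.05). Camera called the list (adjusted p = 3.25e-04; adjusted p = 0.725 with an estimated correlation), and the median stayed between 0.39 and 0.59 with any of the 6 plates left out. Against random lists of matched expression the list lay inside the central 95% in both cell types (91.8th percentile in bled HSC and 88.9th in bled MPP1). In HSC plate 3 the same list was lower than in HSC plates 1 and 2, by a median of -0.49. Camera also called ribosomal proteins (17 of 20 higher, median 0.23, adjusted p = 0.0165), the unfolded protein response (11 of 17 higher, 0.42, 0.0354) and glycolysis (13 of 16 higher, 0.34, 0.0461). Hspa5, the chaperone BiP, differed by 1.12 (SE 0.35) and Gapdh by 1.18 (SE 0.37), and with an estimated correlation these lists had adjusted p = 0.771, 0.725 and 0.725. Against random lists they lay inside the central 95% as well, at the 85.7th, 96.4th and 84.2nd percentile in bled HSC and the 15.8th, 75.0th and 77.6th in bled MPP1, where the median of ribosomal proteins was 0.06. Without the bled HSC plate none of these 3 lists was called (adjusted p = 0.883, 0.883 and 0.870), and without HSC plate 2 none either (medians 0.01, 0.32 and 0.49). The calls of the unfolded protein response and of glycolysis also ended without HSC plate 1 (adjusted p = 0.0611 and 0.119) and without MPP1 plate 1 (0.0671 and 0.152).

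G2/M genes were lower after bleeding in 22 of 24 cases, with a median of -0.90 (camera adjusted p = 3.48e-05; adjusted p = 0.725 with an estimated correlation; 0 genes adjusted over the list alone and 2 at an unadjusted limma p under 0.05). Ube2c, which marks mitotic proteins for degradation, was at 0.146 FPKM in bled HSC against 13.3 ± 3.34 in HSC, and at 29.9 in bled MPP1 against 33.8 ± 14.0 in MPP1 (SD, n = 2 plates each). The difference lay in the bled HSC plate: its median was -1.80 below HSC plates 1 and 2, lower than every one of 10000 random lists, and without it the median was -0.02 (adjusted p = 0.883). HSC plate 3 was as low, with a median of -1.94, also at the 0th percentile of random lists. The share of cells with at least 3 G2/M genes was 8.33% (exact interval 2.32 to 20.0) in bled HSC and 56.0% (41.3 to 70.0) in bled MPP1, with 0% and 13.8% in their no-cell wells. Between the bled plates, MPP1 exceeded HSC by a median of 2.07 for G2/M genes and 1.43 for S phase genes (21 of 21 higher), both above all 10000 random lists.

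Immediate early genes were higher after bleeding in 13 of 16 cases (median 0.62, camera adjusted p = 0.0165; adjusted p = 0.733 with an estimated correlation). Against their normal plates 1 and 2, the median was 1.52 in bled HSC (above all 10000 random lists) and -0.51 in bled MPP1 (0.08th percentile), 1 plate each. Atf3 was at 117 FPKM in bled HSC against 7.77 ± 2.41 in HSC, and at 28.4 in bled MPP1 against 44.0 ± 12.7 in MPP1 (SD, n = 2 plates each). HSC plate 3 was higher than HSC plates 1 and 2 by a median of 0.68, also at the 100th percentile of random lists. The call ended without HSC plate 1 (median 0.41, adjusted p = 0.184) and without HSC plate 2 (median 0.58), and without the bled HSC plate the median was -0.51 (adjusted p = 0.0852). S phase genes had a median of -0.37 in bled HSC (percentile 3.32 among random lists, inside the central 95%) and 0.89 in bled MPP1 (99.96th percentile, 19 of 21 higher); over both, camera gave adjusted p = 0.172 (median 0.29). In HSC plate 3 they were lower than in HSC plates 1 and 2 by a median of -1.03 (0.05th percentile). Interferon genes had a median of -0.95 in bled HSC (0.16th percentile) and 0.32 in bled MPP1 (84.0th percentile). Over both, camera gave adjusted p = 0.103 (median -0.57). Interferon genes were also lower in HSC plate 3 than in HSC plates 1 and 2, by a median of -1.22 (1 higher, 18 lower, 0.06th percentile).

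The T and NK list was called as higher after bleeding (4 of 4 tested genes, median 1.83). Camera gave adjusted p = 0.00360, and adjusted p = 0.725 with an estimated correlation. The filter on mean FPKM kept 4 of 11 matched genes over the 6 plates, but 1, Klrb1c, over the 4 normal plates. Cd3d, Thy1 and Cd247 entered through the bled plates, so a call as higher was largely set by the filter. The call also rested on few cells. Cd3d, a subunit of the T cell receptor complex, was detected in 1 of 48 cells of the bled HSC plate. That cell held 6 of the list's genes, with Cd3d at 1473 FPKM and Kit and Ly6a listed at 0. Klrb1c, an NK cell receptor of the same list, was detected in 7 of 48 bled HSC cells. On HSC plates 1, 2 and 3 it was detected in 2 of 50, 0 of 53 and 3 of 73 cells. In bled MPP1 its mean was 0.192 FPKM, against 2.93 and 2.29 on MPP1 plates 1 and 2. Over both cell types limma gave p = 0.177 for its mean level, which does not test these shares of cells. Without the cell that held 6 of the list's genes, left out after seeing the data, the median of the list in bled HSC relative to HSC plates 1 and 2 was 0.50 in place of 4.42. Without the bled HSC plate too few genes of the list remained for a test.

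The other lists were not called between bled and normal plates. Camera gave adjusted p = 0.216 for erythroid genes (median -0.72, and -1.20 in bled HSC, percentile 0.31 among random lists), 0.234 for heme synthesis and iron (0.52), 0.854 for megakaryocyte genes (-0.04), 0.854 for granulocyte-monocyte genes (0.03), 0.898 for lymphoid genes (0.66), 0.723 for B and plasma genes (0.28), 0.489 for macrophage genes (0.84), 0.697 for housekeeping genes (0.04) and 0.918 for sort markers (median 0.19, mean -0.06, camera's direction up). For the HSC program (median -0.13, mean 0.14, adjusted p = 0.413) and the quiescence regulators (median -0.04, mean 0.25, adjusted p = 0.924) the direction of camera was up, opposite to the median. By cell type, quiescence regulators had a median of 0.21 in bled HSC (percentile 71.7 among random lists) and -0.65 in bled MPP1 (percentile 0.22). Heme synthesis and iron genes had 0.67 in bled HSC (percentile 98.5). In bled MPP1, macrophage genes had 2.44 (3 genes, percentile 99.7) and housekeeping genes -0.21 (percentile 1.40). HSC plate 3 had -0.57 for erythroid genes against HSC plates 1 and 2 (9 of 9 lower, percentile 16.05). For heme genes it had 0.50 (percentile 98.9). S100a8 (neutrophil list) differed by -2.11, Cpa3 (mast cells and basophils) by -0.48 and Emcn (endothelium and stroma) by 0.14, each the 1 measured gene of its list and none past limma.

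By size alone, with no test, the genes far above both normal plates in bled HSC included Cxcl9, Odf3l1, Cd3d and Xcl1, each detected in 4.17% of cells or fewer. The farthest below were Zfp959, Cdk5rap1, Irf5, BC023829 and Clnk. In bled MPP1 the farthest above were Dip2a, Rnase12, Chchd8, Jazf1 and Srsf6. Dip2a, Rnase12, Chchd8 and Jazf1 were detected in 6.00%, 4.00%, 14.0% and 10.0% of bled MPP1 cells. Srsf6, a splicing factor, was detected in 68.0% of bled MPP1 cells at a mean of 596 FPKM, against 31.2 and 26.8 in MPP1 plates 1 and 2. The farthest below were Gadd45g, Cdkn2c, Nek6, Tnfrsf12a and Mafk, of which Gadd45g, a growth arrest gene, was at 0.726 FPKM against 21.6 and 18.1 in MPP1 plates 1 and 2. Gadd45g was detected in 10.0% of bled MPP1 cells, against 15.7% and 20.8% on MPP1 plates 1 and 2. The bled HSC plate lay outside HSC plates 1 and 2 by at least 1 log2 unit in 1103 genes (522 above and 581 below), the bled MPP1 plate outside the MPP1 plates in 824, and HSC plate 3 outside HSC plates 1 and 2 in 1067. HSC plate 1 lay outside HSC plates 2 and 3 in 1009 genes, and HSC plate 2 outside plates 1 and 3 in 793.

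Cells of 1 population were next compared with each other. Genes of 5 lists co-varied between cells on 7 of 7 plates: ribosomal proteins (mean pairwise Spearman r over plates 0.404, against 0.0555 in random lists), G2/M phase (0.378 against 0.00333), S phase (0.218 against 0.00512), immediate early genes (0.141 against 0.0219) and interferon response genes (0.128 against 0.00314). Megakaryocyte genes co-varied on 5 plates (0.0604 against 0.00305), and granulocyte-monocyte genes (0.0875) and housekeeping genes (0.124) on 4 each. The HSC program co-varied on 3 plates (0.0261 against 0.0105), erythroid genes on 2 of 6, oxidative phosphorylation and the unfolded protein response on 2, glycolysis, heme synthesis and sort markers on 1, and quiescence regulators and lymphoid genes on 0. No p is given, because cells are not replicates.

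The 18 bulk populations, 1 library each and so without a test, placed the lists along the lineages. The HSC program had its highest mean in HSC (mean log2 level 2.37), followed by MPP1 (1.85). Erythroid genes were highest in pro-erythrocytes (5.40), where Cpox, an enzyme of heme synthesis, reached 1095 FPKM against 0.0926 in HSC, and Tfrc, the transferrin receptor, 213 against 0.191. Heme synthesis and iron genes (4.54), S phase genes (4.93) and G2/M genes (3.33) were also highest there. Granulocyte-monocyte genes were highest in the GMP gates (4.86 in GMP-11 and 4.82 in GMP-7); the neutrophil elastase gene Ela2 reached 2932 FPKM in GMP-11 and was listed at 0 in HSC, and Mpo, myeloperoxidase, reached 1257 against 0.212. Lymphoid genes were highest in common lymphoid progenitors (CLP, 4.27), with Ebf1, a B cell transcription factor, at 1726 FPKM there and listed at 0 in 8 populations. Megakaryocyte genes were highest in megakaryocyte progenitors (MKP, 3.22), with Gp5, a platelet glycoprotein, at 147 FPKM.

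Other groups followed less simple paths. Immediate early genes were highest in the Sca1-high CLP gate (3.33), with Jun at 700 FPKM there and 0.0151 in HSC. Quiescence regulators were highest in PreCFU-E (2.26) and lowest in HSC (0.768), and the unfolded protein response was highest in GMP-7 (5.66) and lowest in HSC (2.21). The HSC library held 2866 genes at FPKM 1, against 5409 in PreCFU-E and 6080 in GMP-7, and what this did to list levels was not tested. Ribosomal proteins were highest in MPP1 and HSC (5.23 and 5.18). Glycolysis (4.11) was highest in GMP-11, oxidative phosphorylation (4.36) and housekeeping genes (5.98) in GMP-7, interferon genes in MPP4, with Oasl2 at 241 FPKM, and sort markers in CMP (2.86). Markers of B and plasma cells (2.77) and of T and NK cells (1.37) were highest in the Sca1-high CLP gate, with Igj, the joining chain of secreted antibodies, at 815 FPKM there. Markers of neutrophils (1.66), macrophages, mast cells and basophils (2.77) and endothelium and stroma (0.789) were highest in mature megakaryocytes, where Mertk, a receptor of phagocytes, reached 941 FPKM. Of 391 pairs of list and population, 128 lay outside the central 95% of random lists in their median difference from HSC (42 above and 86 below). With quantile normalization 80 did (43 above and 37 below). Random lists tied with a list did not count as below it, so the 86 can include pairs with no median difference from HSC.

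Of the sort markers, Flt3 (CD135) was highest in CLP and MPP4 (376 and 231 FPKM) and at 0.332 in HSC, and Itga2b (CD41) was highest in MKP (70.5 FPKM). Cd34 was at 1786 FPKM in MPP1 and 25.2 in HSC, although the label of the bulk HSC library gives the same CD34+ gate as that of MPP1. Kit was highest in preMegE (644 FPKM). Ly6a reached at most 5.81 FPKM, in the Sca1-high CLP gate. It was at 0.0803 FPKM in bulk HSC and 0.626 in bulk MPP1, both low and opposite in direction to the single cells.

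**Figure D4:**
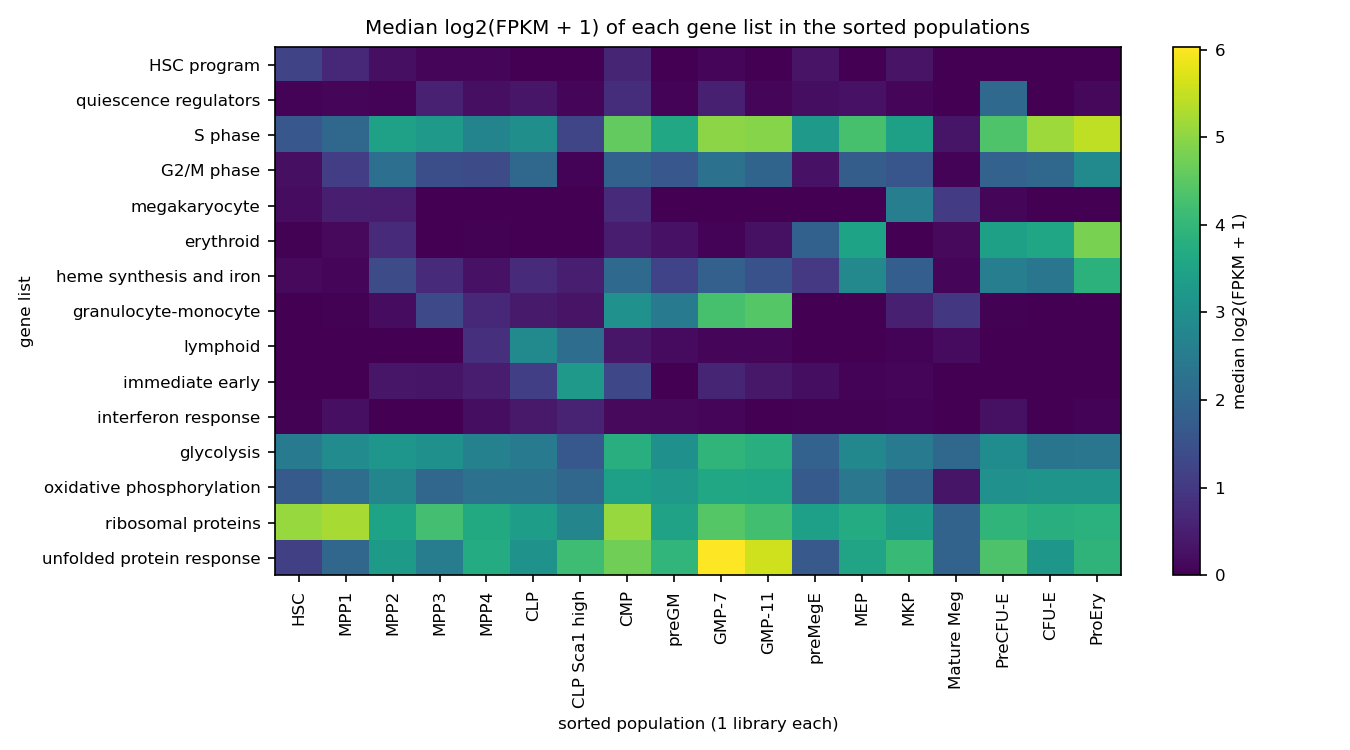
Median log2(FPKM + 1) of 15 gene lists (vertical axis) in 18 sorted bulk populations (horizontal axis), 1 library each; brighter is higher. Erythroid genes are brightest in pro-erythrocytes (median 4.83), granulocyte-monocyte genes in GMP-11 (4.43), lymphoid genes in CLP (2.87) and megakaryocyte genes in MKP (2.58).

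Between bulk HSC and MPP1, 1574 genes differed at least 4-fold (890 higher and 684 lower in MPP1). The largest differences were in Fdft1, B3bp, Ube2q1, Tnfaip3 and Errfi1, higher in MPP1, and in Ngfrap1, Scyl2, B4galt5, Ank and Strap, lower. Tnfaip3, an inhibitor of NF-kB signalling, was at 21.5 FPKM in HSC and 3309 in MPP1, and Fdft1, squalene synthase, at 0.0311 and 410. GMP-7 and GMP-11, gates for the same progenitor, differed in 1310 genes, the fewest of 153 pairs (median 2073, most 3138), and CLP and Sca1-high CLP in 1891. Single transcripts weighed heavily in some libraries: a transcript without a gene symbol took 42.9% of all FPKM in GMP-11 and 34.4% in preMegE, and Cox4i1 took 24.4% in MPP1.

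Finally, the bulk and the single-cell difference between MPP1 and HSC were set side by side over 9156 genes. Across genes, which are not independent replicates, Pearson's r was 0.0250 and Spearman's rho 0.0422 (permutation p = 0.0150 for Pearson's r). The sign was the same in 46.3% of genes. Genes with no difference in bulk counted as not having the same sign, so this share cannot be set against an even split. G2/M genes had a median of 0.46 in bulk and 0.55 in single cells over the 23 genes in both, and S phase genes 0.83 and 0.23. HSC program genes had -0.19 and -0.67, with the same sign in 11 of 22 genes. Ifitm1, lower in MPP1 in single cells, was at 37.0 FPKM in bulk HSC and 202 in bulk MPP1. Interferon genes had a bulk median of 0 (7 higher and 6 lower of 18) where the single-cell median was -1.86, and immediate early genes also 0 in bulk against 1.61. The levels themselves correlated across genes with r between 0.306 and 0.396 for bulk library and plate.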

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

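The interaction tests in this part, the test of no-cell wells for the immediate early genes and the test without the bled HSC plate were chosen only after the results were seen; the other 6 tests were written down before.

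Interferon response genes were lower in MPP1 than in HSC plates 1 and 2 (median -1.84 over 19 genes). Against 1 plate as the cause, the median was -1.82 or lower with any of the 4 plates left out, and against a few cells with very high values, the mean share of cells with a list gene was at least 12.3 percentage points higher in each of HSC plates 1 and 2 than in each MPP1 plate. Background RNA in the wells stays open: the no-cell wells differed the same way by 0.77 (bootstrap SE 0.31), which is not below 0.92, the bound written before, by more than its error. This error is over the genes of the list, not over wells or plates. The median log2 level of no-cell wells was 2.02 on HSC plate 1 and 0 on HSC plate 2 and on both MPP1 plates. HSC plate 3, from a separate table, was lower than HSC plates 1 and 2 by a median of -1.22, with a mean share of 13.1% of cells against 11.4% and 11.3% in MPP1, so a difference between plates or mice is open as well. A difference between the cell types is named by the design, and was not tested apart from the plates.

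Immediate early genes were higher in MPP1 (median 1.53 over 16 genes). Leaving out any of the 4 plates left a median of at least 1.26, which argues against 1 plate. Between the bled plates, 1 each, the list differed the other way, by a median of -0.61 (5 genes higher in MPP1, 11 lower). Background RNA in the wells is a candidate explanation, because the no-cell wells differed by 3.27 (bootstrap SE 0.80 over the genes of the list), more than the wells with 1 cell. However, 6 of 28 and 4 of 13 such wells on MPP1 plates 1 and 2 held 1000 or more genes, so wrong labels of cell number are open too. A general stress of handling cannot be told apart: heat shock genes had a median of 0.34, between the bounds written before, with 8 of 9 higher in MPP1. A difference between the cell types stays open and untested.

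The bled plates differed from the normal plates in several gene groups. Plates made separately are a candidate explanation, since the bled HSC plate had 1.03 times as many genes outside HSC plates 1 and 2 as HSC plate 3, whose growth note names normal and bled mice together. HSC plate 1 stood outside HSC plates 2 and 3 in 1009 genes, so a difference between any 2 plates, made separately or not, is open as well. The G2/M difference may rest on 1 plate, as its median without the bled HSC plate was -0.0223. Bleeding itself is named by the design and stays open, because each bled group is 1 plate in another table.

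The bled minus normal effect in MPP1 minus that in HSC was tested with camera as an interaction in 20 lists, over 6 plates with 2 residual degrees of freedom, and passed in 4 lists at the preset correlation. Each bled group is 1 plate, assumed to vary like the normal plates, so a difference between plates is not set apart from one between cell types. The median was 1.18 for S phase (adjusted p = 0.00493; adjusted p = 0.558 with an estimated correlation) and 1.52 for G2/M phase (0.00103; adjusted p = 0.720 with an estimated correlation). It was -1.97 for immediate early genes (1.90e-08; adjusted p = 0.488 with an estimated correlation) and -4.05 for the T and NK list (1.77e-04; adjusted p = 0.488 with an estimated correlation). HSC plate 3 was shifted from HSC plates 1 and 2 in the same direction as the bled HSC plate, by medians of -1.03, -1.94 and 0.68 for S phase, G2/M phase and immediate early genes. The T and NK value rests largely on 1 cell of the bled HSC plate, without which the median in bled HSC relative to HSC plates 1 and 2 was 0.50 in place of 4.42, while Klrb1c was detected in 7 of its 48 cells. Of the 4 tested genes of this list only Klrb1c passed the filter on mean FPKM over the normal plates, so the filter favoured this call. Limma called 0 of 10017 genes for the same term, with 511 at an unadjusted p under 0.05. The median of 16 megakaryocyte genes was lower than both normal plates in bled HSC (5 genes higher, 11 lower) and higher than both in bled MPP1 (9 higher, 7 lower), a difference of medians of 0.62 that did not pass the interaction test (camera adjusted p = 0.501). The median of 6 lymphoid genes was higher than both normal plates in bled HSC and lower than both in bled MPP1 (difference of medians -0.89), with 3 genes higher and 3 lower in each, and did not pass either (camera adjusted p = 0.151). In wells that no comparison of cells used, a signal appeared: 20 of 150 wells labelled with no cell held 1000 or more genes.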

How the results depend on the processing

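Added after seeing the data were the tests with genes in 20% of the cells, and for gene lists HSC plate 3 and the filters on wells and on low values; over all alternatives 51 values were weaker, 13 stronger and 2 reversed, and the cause was not tested. For MPP1 against HSC, where limma called 1 gene, the count was 0 with no filter on low values, 6 at FPKM 5 or more, 38 with the plate mean of log2 values, 2 with no filter on wells, 0 with the bled plates added, 7 with genes in 20% of the cells, 70 with both of these changes to averaging and genes, and 0 to 0 in leave-one-out fits (at an unadjusted p under 0.05 there were 776 with no filter, 608 with the bled plates added and 437 to 684 with a plate left out). With the replicate block it was 58 (16 higher and 42 lower); the plate numbers share only a number, and the pairing check gave r = 0.0423 over 2 pairs. For bled against normal plates, where limma called 0, it was 6 with the mean of log2 values, 2 with no filter on wells, 1 with quantile normalization, 13 with the mean of log2 values and genes in 20% of the cells, and 0 to 1 in leave-one-out fits. With an estimated correlation camera called 0 lists in either comparison: adjusted p = 0.377 for the HSC program, 0.737 for G2/M phase, 0.339 for immediate early and 0.244 for interferon genes between MPP1 and HSC, and 0.725 for G2/M phase and for oxidative phosphorylation after bleeding. The G2/M list of MPP1 against HSC ranged from 1.84e-05 to 0.657 in leave-one-out fits, with its direction reversed without HSC plate 1 (0.652), and had 0.0931 with 2000 genes per well, 0.0576 with no filter on wells and 0.0531 with no filter on low values. After bleeding 2 to 8 lists were called in leave-one-out fits, 3 with no filter on wells and 3 with no filter on low values; G2/M phase ranged from 5.08e-08 to 0.883, and immediate early genes from 6.31e-08 to 0.184, reversed without the bled HSC plate (0.0852). Where a group was left with 1 plate, that plate is assumed to vary like the others. Quantile normalization gave 80 bulk pairs of list and population (43 above and 37 below) in place of 128 (42 and 86), and genes above FPKM 0 gave an exact permutation p of 0.0469 for several cells against 1. Genes at FPKM 5 or more gave r = 0.0201 between bulk and single cells (permutation p = 0.105 in place of 0.0150). A pseudocount of 0.1 gave r = 0.0393 (permutation p = 9.99e-04). Not run were the repeat run of HSC plate 1 in its place, the planned comparison of the 2 runs, and the planned analysis of spike-in noise. What depth limits is unknown, because no counts were used.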

Other observations

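Genes in this part were chosen after their values were seen, and the values carry no further test. Among interferon-inducible genes outside the list, Mpa2l, a guanylate-binding protein, was at 48.5 ± 3.70 FPKM in HSC plates 1 and 2 and 0.393 ± 0.0196 in MPP1 (SD, n = 2 plates each), Gbp10 at 13.6 ± 5.10 and 0.197 ± 0.206, and Tgtp2 at 465 ± 92.5 and 136 ± 30.9. Slfn2, a Schlafen gene, was at 55.5 ± 14.8 and 2.59 ± 1.79. In HSC plate 3, from a separate table, Mpa2l was at 0.928 FPKM, Gbp10 at 0.115, Tgtp2 at 199 and Slfn2 at 36.5.

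Other genes set plates apart by table as well as by group. Wtap, a subunit of the RNA methylation complex, was at 62.5 ± 26.0 FPKM in HSC plates 1 and 2 and 30.9 ± 13.0 in MPP1 (SD, n = 2 plates each), at 208 and 146 in the bled HSC and bled MPP1 plates, and at 229 in HSC plate 3. Mt1, a metal-binding metallothionein, was at 49.9 and 63.1 FPKM in the bled HSC and bled MPP1 plates, and at 7.99 ± 5.93 in HSC, 5.13 ± 4.49 in MPP1 and 2.94 in HSC plate 3. Sla, an adaptor of antigen receptor signalling, was at 7.08 and 7.73 FPKM in the bled plates, against 39.2 ± 0.316 in HSC, 44.4 ± 3.76 in MPP1 and 28.2 in HSC plate 3. Of the B and plasma list, at least 3 genes were detected in 6 of 50 cells of HSC plate 1, 0 of 53 of HSC plate 2, 0 of 73 of HSC plate 3, 2 of 51 and 3 of 48 of MPP1 plates 1 and 2, 5 of 48 of the bled HSC plate and 2 of 50 of the bled MPP1 plate, and Cd74, the MHC class II invariant chain, was at 155 and 12.9 FPKM in HSC plates 1 and 2.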
